A study of Arabidopsis thaliana with 24 samples.

How the data were processed

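Start sites were measured by CAGE in aerial parts of 2-week-old seedlings of 4 Arabidopsis thaliana accessions, per the labels. The 24 libraries fall into 8 groups of 3 replicates (4 accessions by 2 treatments). Per the labels' protocols, plants grew at 22 °C under continuous light of 40 µE, and treated plants had 24 h at 4 °C under 140 µE. RNA was reverse-transcribed with random primers, capped molecules were captured through biotinylated caps, and adaptors were ligated to both cDNA ends. The labels mention no molecular identifiers, so tags may include PCR copies, and binomial intervals cover counting error only.

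The deposited table lists clusters of start sites with their chromosome, strand, ends, width, peak position, tag count and peak tag count. The cluster counts and peak counts are raw whole-number counts that the authors deposited without normalization; the smallest cluster count is 5. The deposited peak ratio is a fraction, the peak count over the cluster count, which holds for 100% of clusters within 1e-08. Positions and widths are in bp per the file headers. Reads were aligned with STAR 2.7.9a, per the submitters' processing notes; the genome build, the filters and the clustering rule are not given in the sources used here. Neighbouring clusters of a set were under 10 bp apart in 0.359% of 317143 gaps, with a jump in number at 10 bp.

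Clusters carry identifiers in 4 separately numbered series whose initials match Altenb-2, Kly-1, Vash-1 and Shigu-2, and the sets are named by accession on that ground alone. No column names a library, a treatment or a replicate, and which libraries each set pools is not given in the sources used here. The comparisons planned before the data were examined therefore could not be made: the response to treatment within and across accessions, its interaction with accession, differences within a treatment, replicate blocks, libraries left out in turn, and model-based tests of promoter usage and gene sets. In their place each accession has 1 pooled value, with no SD, no n and no p-value across genes. Differences are described by a fixed size and, for detection and promoter usage, by what counting error alone would give.

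Coordinates were compared with the TAIR10.1 reference and its annotation. All cluster ends lie within the 5 reference chromosomes, and 70.8% of peaks lie on a pyrimidine-purine step there, against 19.99% at 50 bp from the peaks, 7.67% at 1 bp upstream and 2.93% at 1 bp downstream. Accession sequences were not used here, so tags from diverged regions can be lost or shifted. Near-identical gene copies can exchange tags, since the handling of multiple matches is not given in the sources used here.

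Clusters within 5000 bp of annotated nuclear rRNA genes were set aside: chromosome 2 from 1 to 10945 (200 clusters, 100815 tags) and chromosome 3 from 14192677 to 14204916 (205 clusters, 103591670 tags). CPM is the count scaled to the tags outside these regions. A cluster is genic when its peak lies on the strand of a gene between 500 bp upstream of the annotated start and the start codon. The most upstream annotated start codon of the gene was used, or 200 bp past the start for genes without coding sequence. Other peaks are intragenic, antisense or intergenic, in this order. Motifs were searched in the reference: TATAWA starting −40 to −25 from the peak, with −140 to −125 as control window, and runs of 8 pyrimidines from −60 to −1.

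Clusters of different sets that overlap on a strand by 1 bp were joined into loci, giving 114903. A locus is found in a set at 1 CPM or more, which is 22.5 tags in Altenb-2 and 37.2 tags in Shigu-2. Shares of genic and non-genic loci were compared within 10 bins of mean abundance, with genic bins weighted to the non-genic numbers, and intervals were taken over 1000 resamples of 1-Mb blocks of the genome. The same matching served for peak positions and for variation between sets (SD of log2 levels of 0.5 or more). A lost locus has 5 CPM or more in 3 sets and no listed cluster in the remaining one. Simulated sets with counting error alone were drawn from the pooled levels and the real depths and passed through the same steps; the matched difference was drawn 100 times.

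A gene's level is the sum of its genic tags. Differences are on the scale of log2(CPM + 0.5), each set minus the mean of the other 3, for genes of 5 CPM or more in at least 1 set, and are described at 2-fold; this scale understates differences of low genes. Ratios set a gene's count in a set against the pooled count of the other 3, with an exact binomial interval. Promoter usage covers genes with at least 2 genic loci and 50 tags in every set, and a share change of 50 percentage points is reported with exact binomial intervals.

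The 25 gene lists (374 genes) were fixed before the data were examined: cold-regulated effectors, cold and light regulators, anthocyanin and flavonoid synthesis, photoprotection, light-harvesting antenna, Calvin cycle, chlorophyll synthesis, clock, heat shock, abscisic acid and drought, proline and sugar metabolism, immunity, glucosinolates, flowering time, ribosome, cell expansion, cell cycle, reference genes, root, flower, seed, guard cell, phloem, epidermis and shoot meristem. A list median was placed among 10000 random lists of the same size matched on mean abundance; this describes these 4 sets and is no test of replicated samples. List medians use members of 1 CPM or more on average over the sets, without the 5 CPM minimum; numbers of members spanning 2-fold keep that minimum. Lists with fewer than 3 measured genes (flower, seed and shoot meristem, 1 each) have no percentile.

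Also fixed before the data were examined were the class limits, the 1 and 5 CPM limits, the 10 bins of abundance, and as alternatives a 200 bp window, 0.5 and 5 CPM, 5 bins and thinning to the smallest set. All other settings, and the rules for what is named, were set after the layout of the table was seen, because the planned rules needed tests between libraries: the 3 genes per set with the largest difference, the 4 members per list with the widest range among those at 5 CPM, the 5 genes with the largest usage change, the 3 non-genic loci per class with the highest mean and the 2 with the widest range, and the 4 most abundant losses.

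The steps were tested on simulated data before use. With 100 genes changed 2-fold and 100 changed 4-fold, the median estimated log2 differences were 0.97 and 1.99, and all were estimated at or beyond the midpoint between no change and the true change. Of 198 genes with an exchanged main locus, 99.5% were found, and 221 of 10225 genes without an exchange were called too. After removal of 300 of 5652 non-genic loci from a set, the matched difference was 2.87 points (2.03 to 3.79). Random lists fell outside the central 95% in 5.25% of 400 medians. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

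Alternatives tried after the data were seen were 20 and 50 bins of abundance, loci from peaks chained within 10 bp and 100 bp, bins on the highest set, initiator peaks alone, each set left out, rRNA repeats kept, pseudocounts of 0.1 and 2 CPM, no minimum and 20 CPM, 200 tags for usage, genes above the median abundance for correlations, and scaling by the median of ratios. Scaling by the median of ratios moves all genes of Altenb-2 by 0.15 and of Shigu-2 by −0.16 on the log2 scale; keeping rRNA repeats moves them by −0.24 and 0.27, those of Kly-1 by 0.15 and those of Vash-1 by −0.18. Percentiles are taken among genes moved alike.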

Results

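Transcription start sites were mapped by CAGE, which captures the capped ends of RNA molecules and sequences tags from them, in aerial parts of 2-week-old seedlings of 4 Arabidopsis thaliana accessions (Altenb-2, Kly-1, Vash-1 and Shigu-2). The labels describe 24 libraries in 8 groups of 3 replicates: each accession under control conditions (22 °C, 40 µE per square metre and second) and after 24 h of combined cold and high light (4 °C, 140 µE). The deposited values are tag counts of 317183 start site clusters in 4 separately numbered sets, whose initials match the accessions. Each set is a pool with no library, treatment or replicate column, so each accession has 1 value per cluster, no replicate check exists, and the response to cold and light could not be computed. How many control and treated libraries stand behind each pool is not given in the sources used here, so no difference between sets can be assigned to accession rather than treatment.

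The sets held 49475691 tags (Altenb-2), 52579946 (Kly-1), 62868630 (Shigu-2) and 52308389 (Vash-1). Clusters at the nuclear rRNA gene repeats took 54.6, 44.3, 40.8 and 53.1% of these tags, in the same order, and were set aside. The remaining 316778 clusters held 22462179 tags in Altenb-2, 29311532 in Kly-1, 37230794 in Shigu-2 and 24535666 in Vash-1. Abundances below are CPM, tag counts scaled to the tags outside the rRNA repeats. The smallest listed cluster had 5 tags, or 0.223 CPM in Altenb-2 and 0.134 CPM in Shigu-2, so an unlisted cluster can hold up to 4 tags. All intervals are 95% intervals. They cover counting error only, of tags, clusters or loci, except those of matched differences and of the initiator share of excess clusters, which come from resampling the genome in blocks. Shares over the clusters of all 4 sets can count the same promoter once per set, so their intervals are too narrow.

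The first question, which the series title names, is how genic and non-genic promoters compare. Genic clusters, at annotated gene starts, took 93.4% of the tags and 57.6% of the clusters (182572), with a median of 29 tags. Intragenic clusters, on the sense strand inside genes, made up 34.1% of the clusters and 6.11% of the tags, at a median of 8 tags. Antisense clusters contributed 7.04% of the clusters and 0.363% of the tags, and intergenic clusters 1.23% and 0.131%. Between sets the genic share of tags ranged from 93.2% in Altenb-2 (Wilson interval 93.19 to 93.21%) to 93.7% in Vash-1 (93.65 to 93.67%). Cluster numbers varied more: Shigu-2, the deepest set, had 37529 intragenic clusters against 22455 in Altenb-2, an order that turned when Shigu-2 was thinned to about the tags of Altenb-2 (21341). Antisense clusters were most frequent in Altenb-2, with 7213 against 4271 in Kly-1, 6047 in Shigu-2 and 4758 in Vash-1, although Altenb-2 had the fewest tags.

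**Figure D1:**
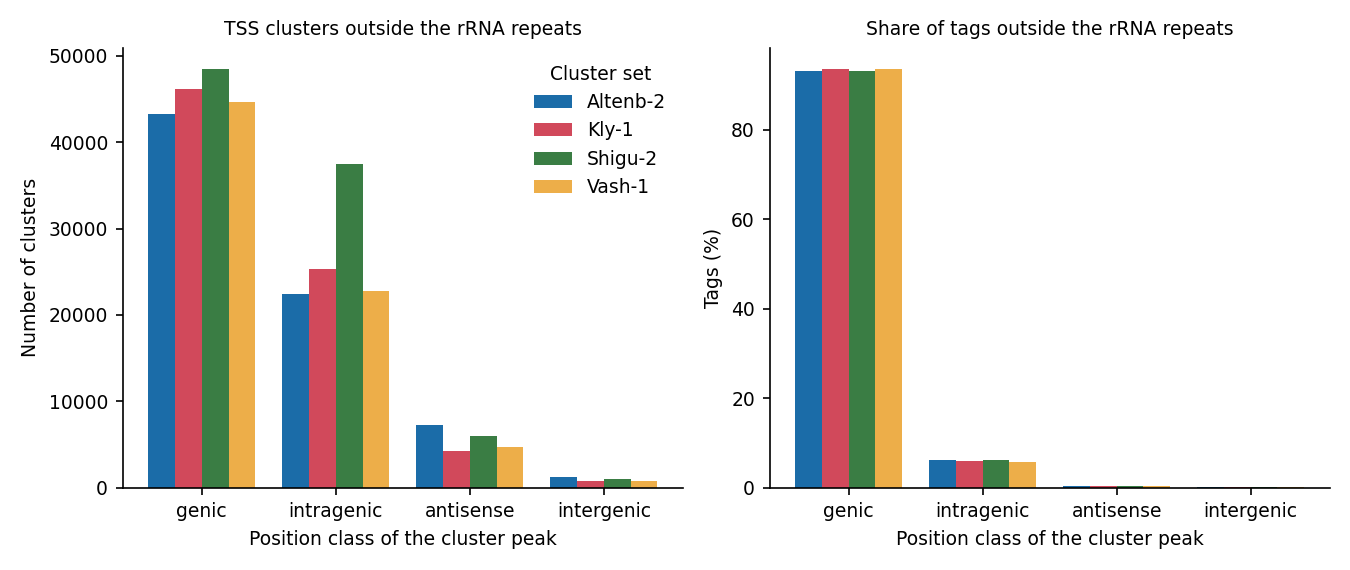
Number of start site clusters (left) and share of tags in percent (right) in each position class, outside the rRNA repeats. Each bar is 1 pooled cluster set, so there is no replicate error; genic clusters held 93.2 to 93.7% of the tags in each set, and Altenb-2 had the most antisense clusters (7213).

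Several non-genic loci were as abundant as strong gene promoters. Intragenic loci lie past the most upstream annotated start codon, so the main promoter of an isoform with a later start codon can be among them. The most abundant intragenic locus lay in CWLP (AT3G22120), which encodes a cell wall and plasma membrane linker protein, at chromosome 3 positions 7795392 to 7796373 on the minus strand, with 4551, 4581, 5771 and 4727 CPM in the order above. Photosystem genes followed: a locus in PSAL (AT4G12800), a photosystem I subunit, had 2684 CPM (Kly-1) to 4247 CPM (Altenb-2), and one in PSBTN (AT3G21055), a photosystem II subunit, had 2080 CPM (Vash-1) to 3215 CPM (Altenb-2). Other non-genic loci were abundant in some sets and far lower elsewhere. An intragenic locus in AREB3 (AT3G56850), a bZIP transcription factor gene, had 60.8 CPM in Altenb-2 and 0.134 to 0.648 CPM in the other 3 sets. Inside ESP (AT1G54040), a locus at chromosome 1 positions 20171635 to 20172004 had 44.3 CPM in Altenb-2 and 14.2 CPM in Vash-1, but 0.307 CPM in Kly-1 and no listed cluster in Shigu-2. Antisense to dNK (AT1G72040), a deoxynucleoside kinase gene, a locus of 4 bp (chromosome 1, 27114198 to 27114201, plus strand) reached 406 CPM in Kly-1 against 1.07 to 1.91 CPM elsewhere. The antisense locus in AT2G04180 had 163 CPM in Altenb-2 and 164 CPM in Vash-1, and 0.819 and 0.725 CPM in Kly-1 and Shigu-2. The antisense locus in PDX1.1 (AT2G38230), a vitamin B6 synthesis gene, was closer to even, at 42.3 to 77.3 CPM.

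Intergenic loci showed the same contrast. A locus at chromosome 5 positions 8953271 to 8953396 (minus strand) was nearly even, at 50.2 to 57.1 CPM. At chromosome 1 positions 21457481 to 21457592 (minus strand), Kly-1 had 274 CPM and the other sets 0.408 to 2.58 CPM. A single-position locus at chromosome 4 position 9297662 (plus strand) had 171 to 237 CPM in Altenb-2, Kly-1 and Vash-1 and 1.18 CPM in Shigu-2. At chromosome 4 positions 7389617 to 7389692 (plus strand), Kly-1 and Vash-1 had 73.3 and 109 CPM, and Altenb-2 and Shigu-2 had 1.29 and 0.242 CPM.

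Genic and intragenic peaks differed in their sequence at the start site. Transcription in plants often starts at a pyrimidine followed by a purine, and 87.0% of genic peaks lay on such a step, against 45.8% of intragenic, 62.4% of antisense and 52.8% of intergenic peaks. At positions 50 bp away from the peaks the share was 19.99%. Intragenic peaks instead carried GG in 22.8% of cases, against 1.03% of genic peaks. The gap narrowed with abundance: among clusters of 5 to 9 tags 81.9% of genic and 40.9% of intragenic peaks had the step, and among those of 1000 or more tags 90.11% (89.6 to 90.6%) and 85.3% (82.9 to 87.5%). Intragenic clusters of protein-coding genes lay in coding sequence in 94.4% of cases, although coding sequence was 55.7% of the length searched. Introns held 4.58% of these clusters at 30.3% of the length, and 3′ untranslated regions 1.01% at 14.0%.

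Upstream core elements were also most frequent at genic loci. A TATA motif (TATAWA starting 40 to 25 bp upstream of the peak) was present at 20.8% of genic loci of 1 CPM or more (20.3 to 21.4%), against 3.71% in a control window 100 bp further upstream. Intragenic loci had it in 7.70% of cases (control window 2.44%), antisense loci in 10.5% (3.14%) and intergenic loci in 14.2% (3.16%). The most frequent motif start at genic loci was −33, at 4.84% of loci. Runs of 8 pyrimidines within 60 bp upstream were found at 44.5% of genic, 28.0% of intragenic, 30.3% of antisense and 35.1% of intergenic loci. For comparison, purine runs were found at 25.5, 26.2, 22.0 and 27.5% in the same order, so the intragenic share was near that of purine runs. Main peaks of 16151 protein-coding genes lay a median of 91 bp downstream of the annotated gene start, and 93.7% lay downstream of it.

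**Figure D2:**
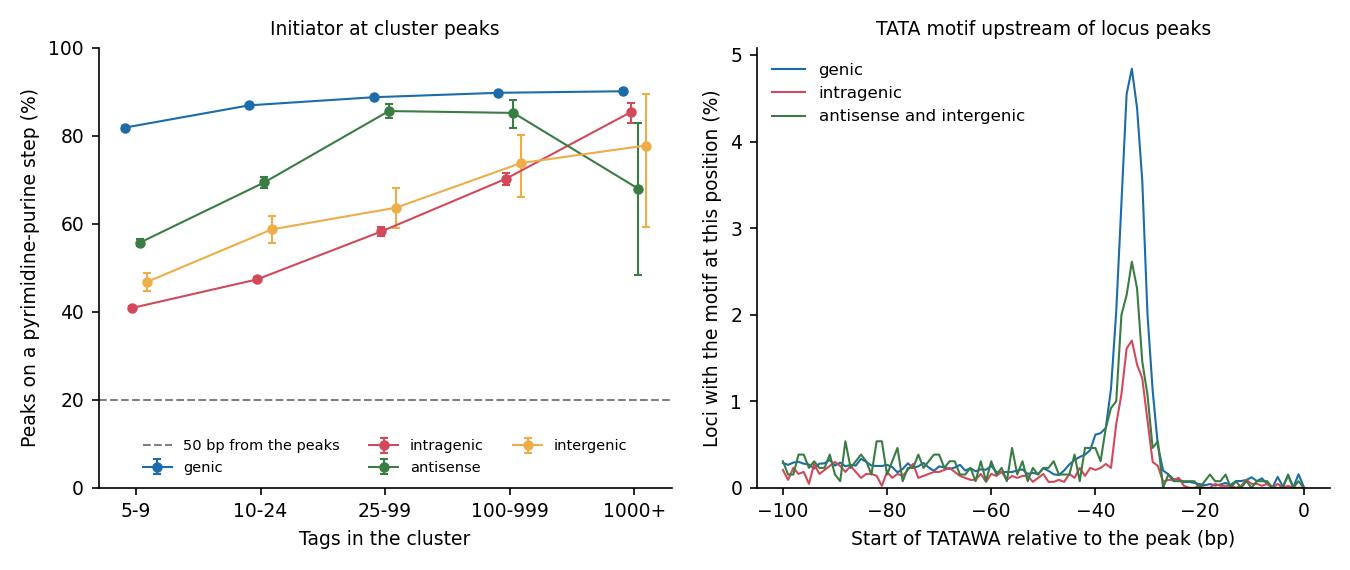
Left, share of cluster peaks on a pyrimidine-purine step (percent, with Wilson intervals) by number of tags in the cluster, for the 4 position classes; the dashed line is the share 50 bp from the peaks (19.99%). Right, share of loci of 1 CPM or more with TATAWA starting at each position relative to the peak (bp): all 3 curves rise near −33, where genic loci reach 4.84%.

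The arrangement at 4 abundant promoters, chosen after their values were seen, is given in the reference sequence. At COR15A (AT2G42540), encoding a chloroplast protein of cold tolerance, the main peak was at chromosome 2 position 17712050 on the minus strand, 280 bp inside the annotated gene start. The sequence from 45 bp upstream to 10 bp downstream of it (17712095 to 17712040) is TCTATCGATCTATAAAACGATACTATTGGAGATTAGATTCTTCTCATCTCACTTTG, with TATAAA at −35. At LTI30 (AT3G50970), a dehydrin gene, the peak at chromosome 3 position 18940739 (plus strand, 96 bp inside the gene start) lies in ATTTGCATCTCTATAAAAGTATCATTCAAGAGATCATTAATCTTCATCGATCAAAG, with TATAAA at −34. ELIP1 (AT3G22840), an early light-induced protein gene, had its peak at chromosome 3 position 8085560 (minus strand, 109 bp inside the gene start), in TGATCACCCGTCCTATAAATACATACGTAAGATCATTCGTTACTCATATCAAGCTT with TATAAA at −32. RBCS1A (AT1G67090), a small subunit gene of Rubisco, had its peak at chromosome 1 position 25049275 (minus strand, 392 bp inside the gene start), in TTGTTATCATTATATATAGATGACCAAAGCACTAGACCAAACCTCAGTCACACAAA with TATATA at −35.

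The second question is whether a promoter seen in one accession was also seen in the others. Overlapping clusters of the 4 sets formed 114903 loci, of which 28621 reached 1 CPM in at least 1 set. Of these, 74.7% of 22969 genic loci reached 1 CPM in all 4 sets (Wilson interval 74.1 to 75.2%), against 44.3% of 4350 intragenic (42.8 to 45.8%), 24.9% of 986 antisense (22.3 to 27.7%) and 10.4% of 316 intergenic loci (7.53 to 14.3%). Non-genic loci together reached it in 39.0% of 5652 cases. Loci at 1 CPM in a single set numbered 1099 in Altenb-2, 800 in Kly-1, 1237 in Shigu-2 and 1232 in Vash-1. The antisense ones among them were most frequent in Altenb-2 (192, against 61, 81 and 104 in Kly-1, Shigu-2 and Vash-1).

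Non-genic loci carried fewer tags, and most of the gap was gone at matched abundance. The matching used the mean of the same 4 levels that decide detection, so a locus missing from a set also falls to a lower bin. In sets simulated with counting error alone, 89.9% of genic and 71.8% of non-genic loci were found in all 4 sets. The real shares were 74.7 and 39.0%, so these draws left a smaller gap than the real one. The draws hold no variation between sets, so the smaller gap does not show whether abundance explains the real one. With genic loci weighted to the abundances of the non-genic ones, 41.1% of genic against 39.0% of non-genic loci were found in all 4 sets, a difference of 2.08 percentage points (1.12 to 3.07). In the lowest 2 of 10 bins of abundance a locus can hardly reach 1 CPM in all 4 sets; over the other 8 bins (3278 non-genic loci) the difference was 3.65 points. By class, the matched difference was 18.4 points for intergenic loci (14.1 to 22.5), 5.97 for antisense loci (3.75 to 8.16) and 0.0807 for intragenic loci (−0.938 to 0.992). The intragenic interval held 0, but it lay above 0 at 5 CPM (2.33), with 5 bins (1.16), with peaks chained within 10 bp (1.79) and 100 bp (1.98), and with bins on the highest set (2.14). Between 14.1 and 25.3 CPM, 98.9% of genic and 90.9% of non-genic loci were found in all 4 sets, and in the highest bin 99.9 and 97.9%. Counting error alone, simulated, left a matched difference of 0.463 points (−0.291 to 1.19); 100 repeats of the simulation gave −0.549 to 1.53 points for all non-genic loci, which overlaps the interval above, and −1.34 to 2.82 points for antisense and intergenic loci together. The size depended on the settings: the difference of genic and all non-genic loci was 4.37 points at 5 CPM, 3.23 with 5 bins, 1.70 with 20, 1.68 with 50, 3.20 with initiator peaks alone, 3.88 with peaks chained within 100 bp, 5.97 with bins on the highest set and 1.38 with rRNA repeats kept. For antisense and intergenic loci together it was 8.75 points (6.52 to 10.8), which became 15.9 at 5 CPM, 19.4 with bins on the highest set and 0.991 (−0.711 to 2.67), no longer above 0 with peaks chained within 10 bp.

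**Figure D3:**
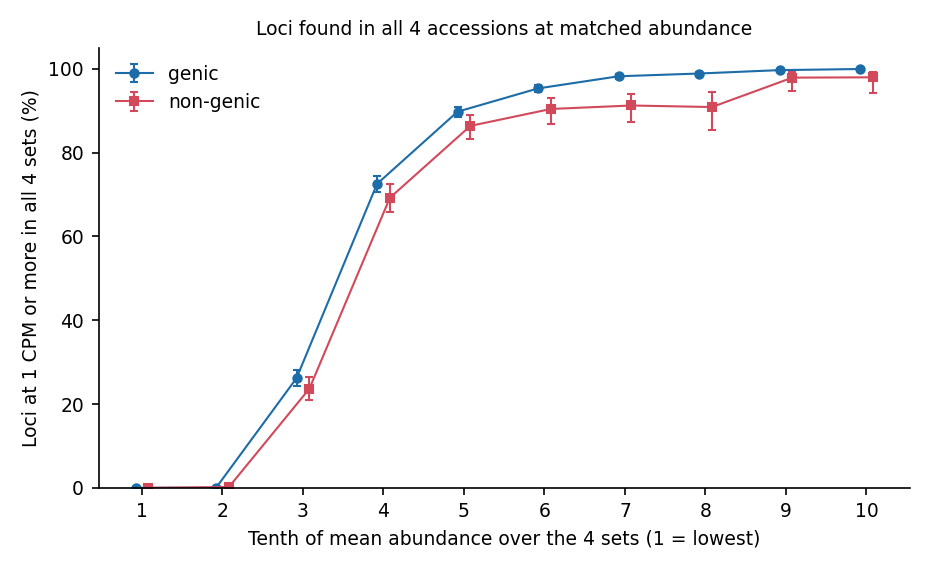
Share of loci at 1 CPM or more in all 4 cluster sets (percent, with Wilson intervals) in each of 10 bins of mean abundance, for genic and non-genic loci of 1 CPM or more in at least 1 set. Both curves start at 0 or near it by construction; in bin 8 (14.1 to 25.3 CPM) genic loci reach 98.9% and non-genic loci 90.9%.

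Genic promoters also kept the position of their main peak more often than intragenic ones. Among loci at 1 CPM in all 4 sets, the highest peak lay at the same base pair in every set for 62.8% of 17149 genic loci (62.1 to 63.5%) and 45.03% of 2205 non-genic loci (43.0 to 47.1%), most of which were intragenic (43.3% of 1926). Antisense loci had 54.9% of 246 (48.6 to 61.0%), and intergenic loci 72.7% of 33 (55.8 to 84.9%). Allowing 5 bp raised the shares to 72.7 and 55.6%. At matched abundance the difference of genic and all non-genic loci was 13.7 points (11.1 to 16.1). The matched genic share was 58.8%, inside the antisense interval, and antisense loci were not matched on their own. The matched difference of all non-genic loci depended on the settings. It was smaller at 5 CPM (3.82 points, 0.0095 to 7.29), with initiator peaks alone (8.23) and with peaks chained within 10 bp (2.69, 0.104 to 5.13).

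Strong loci with no listed cluster in 1 set were few. Of 13072 loci with 5 CPM or more in 3 sets, 25 had no listed cluster in the remaining set: 18 of 12162 genic loci (0.148%, 0.0936 to 0.234%) and 7 of 910 non-genic loci (0.769%, 0.373 to 1.58%). Vash-1 lacked 12 of them, Kly-1 6, Altenb-2 4 and Shigu-2 3. The 18 genic loci belonged to 17 genes, and only 9 pairs of gene and set had no listed genic cluster at all. Elsewhere the gene kept another genic cluster, as did INDH and AT3G43610 below. Drops that left a listed cluster are not counted, such as that at chromosome 4 position 9297662 (44 tags in Shigu-2). An intragenic locus in HISN5B (AT4G14910), a histidine synthesis gene, at chromosome 4 position 8529088 averaged 27.1 CPM elsewhere and was unlisted in Kly-1. Genic loci of AT3G22235 (25.3 CPM elsewhere, unlisted in Vash-1), AT4G02825 (22.2 CPM, Kly-1) and PUR7 (AT3G21110, a purine synthesis gene, 16.2 CPM, Altenb-2) were the most abundant of the genic ones. With peaks chained within 10 bp the count was 1565, and with rRNA repeats kept it was 5.

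The third question concerns levels of whole genes, taken as the sum of their genic tags. Clusters were listed at 20837 genes, 19443 of them among the 27444 annotated protein-coding genes, and 17585 genes were listed in all 4 sets. Of 13826 genes at 5 CPM or more in at least 1 set, 3146 differed 2-fold or more between the highest and lowest set. Against the mean of the other 3 sets, 345 genes were higher by 2-fold and 616 lower in Altenb-2, 520 and 352 in Kly-1, 500 and 479 in Shigu-2, and 483 and 555 in Vash-1. These directions depended on scaling: genes higher in Altenb-2 were 35.9% of its 2-fold genes, but 49.8% with scaling by the median of ratios and 18.202% with rRNA repeats kept, and in Shigu-2 the shares were 51.1, 37.2 and 74.8%. Across 16648 genes, which are not independent replicates, log2 levels correlated at Pearson r of 0.921 (Shigu-2 with Vash-1, Spearman rho 0.929) to 0.945 (Kly-1 with Shigu-2, 0.951). Without a minimum level, 5426 genes spanned 2-fold, and at 20 CPM 1570.

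The widest single-gene differences approached presence against absence. AT5G26270 (chromosome 5, 9206375 to 9208136) had 770 CPM in Altenb-2 and 1.93 to 3.14 CPM elsewhere, a ratio to the pooled others of 306 (269 to 350). The pseudogenes AT5G33251 and AT5G63941 had 263 and 153 CPM in Altenb-2, at ratios of 479 (363 to 646) and 258 (197 to 344). Kly-1 lacked most tags of SNC1 (AT4G16890; chromosome 4, 9500271 to 9505972), an immune receptor gene: 1.33 CPM against 288, 172 and 122 CPM in Altenb-2, Shigu-2 and Vash-1, a ratio of 0.00706 (0.00502 to 0.00966). The non-coding gene AT4G15242 had 80.5 CPM in Kly-1, none listed in Altenb-2, and a ratio of 377 (238 to 637), and AT5G34869 had 42.9 CPM (1257 tags) in Kly-1 and was unlisted in the other sets. In Shigu-2, ESP, whose product diverts glucosinolate breakdown towards nitriles, had 6.45 CPM against 2956 CPM in Altenb-2, 124 CPM in Kly-1 and 1156 CPM in Vash-1 (log2 difference −6.76; chromosome 1, 20170715 to 20173949). Shigu-2 also had 2.01 CPM of the non-coding AT4G13495, against 139 to 598 CPM elsewhere, and 1058 CPM of AT3G62530, against 9.21 to 15.2 CPM (ratio 88.2, 82.6 to 94.2). In Vash-1, AT3G44430 had 197 CPM (ratio 170, 140 to 209), AT5G28919 had 74.9 CPM (ratio 128, 97.3 to 172), and AT3G00470 had 74.3 CPM (1824 tags) with no listed cluster elsewhere. Tags of a gene that is diverged in, or missing from, an accession cannot map to the reference, so a low value is a low mapped count.

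Gene lists for cold, light, metabolism, defence and tissue identity were compared by their median log2 difference, each set minus the mean of the other 3, placed among 10000 random lists of similar abundance. Medians are over members of 1 CPM or more on average, and the numbers of members spanning 2-fold are of those at 5 CPM or more in at least 1 set. Of 88 such medians over 22 lists, 31 lay outside the central 95%, as did 11 of 22 medians of the range between sets. Cold-regulated effectors, the proteins that protect cells in the cold, were highest in Shigu-2 (median 0.79, percentile 100) and lower in Altenb-2 (−0.40, 0.11) and Vash-1 (−0.28, 0), and 12 of 21 members spanned 2-fold. LTI30 had 2082 CPM in Shigu-2 against 1022, 902 and 449 CPM in Altenb-2, Kly-1 and Vash-1. GOLS3 (AT1G09350), a galactinol synthase gene, had 405 CPM in Shigu-2 and 257 CPM in Kly-1 against 113 and 110 CPM in Altenb-2 and Vash-1. KIN1 (AT5G15960) ranged from 170 CPM in Vash-1 to 765 CPM in Shigu-2, and GRP8 (AT4G39260), a clock-controlled RNA-binding protein gene, from 23.4 CPM in Vash-1 to 191 CPM in Shigu-2. The list median of Kly-1 (0.17, percentile 99.1) moved inside the central 95% when tags were thinned to the smallest set (0.12). The share of tags in the rRNA repeats ran the other way, lowest in Shigu-2 (40.8%) and highest in Altenb-2 (54.6%).

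Regulators of the cold and light response were lower in Vash-1 (−0.34, percentile 0.15), a call lost with rRNA repeats kept (−0.38), and spread widely between sets (median range 0.95, percentile 99.2), with 7 of 13 members spanning 2-fold. CBF3 (AT4G25480), an activator of cold-regulated genes, had 15.7 CPM in Shigu-2 and 4.59 to 7.37 CPM elsewhere. RAP2.1 (AT1G46768) and HSFC1 (AT3G24520) were likewise highest in Shigu-2 (100.2 and 62.1 CPM) and lowest in Vash-1 (43.98 and 26.1 CPM). ZAT10 (AT1G27730), a zinc finger repressor, instead had 202 CPM in Kly-1 and 74.1 CPM in Shigu-2.

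Photoprotection genes were higher in Shigu-2 (0.36, percentile 99.7) and lower in Altenb-2 (−0.34, 1.31), again opposite to the rRNA share, and 6 of 20 spanned 2-fold. ELIP1 had 1768 CPM in Shigu-2 against 513 CPM in Altenb-2, with 1038 and 856 CPM in Kly-1 and Vash-1. ELIP2 (AT4G14690) had 1491 CPM in Shigu-2 and 582 CPM in Vash-1, LIL3.1 (AT4G17600) 347 CPM in Shigu-2 and 112 CPM in Kly-1, and FTSH8 (AT1G06430), a thylakoid protease gene, 85.4 CPM in Shigu-2 and 32.8 CPM in Altenb-2. Light-harvesting antenna genes showed the reverse, higher in Altenb-2 (0.45, percentile 100) and lower in Shigu-2 (−0.59, 0), with 7 of 18 spanning 2-fold, and their medians ran with the rRNA share in all 4 sets (0.17 in Vash-1, 0.0069 in Kly-1). LHCB3 (AT5G54270) had 9279 CPM in Altenb-2, 8252 CPM in Vash-1, 6292 CPM in Kly-1 and 3561 CPM in Shigu-2, and LHCB1.4 (AT2G34430) ran from 3939 CPM in Shigu-2 to 10264 CPM in Altenb-2. LHCB1.2 (AT1G29910) followed, from 2800.0 to 6829 CPM, while LHCA6 (AT1G19150) was highest in Vash-1 (97.8 CPM against 34.0 CPM in Shigu-2).

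Chlorophyll synthesis genes were lower in Shigu-2 (−0.29, percentile 0.65), with 0 of 12 spanning 2-fold: CRD1 (AT3G56940) had 1174 CPM in Shigu-2 and 1723 to 1939 CPM elsewhere, and PORB (AT4G27440) 517 CPM in Vash-1 to 1022 CPM in Kly-1. Calvin cycle genes were higher in Vash-1 (0.23, percentile 98.7) and lower in Shigu-2 (−0.21, 1.85); with rRNA repeats kept the Shigu-2 median reversed to 0.06. Of its 15 members, 3 spanned 2-fold, and all 3 were Rubisco small subunit genes in 1 tandem array on chromosome 5. RBCS1B (AT5G38430) had 1592 CPM in Kly-1 and 765 CPM in Altenb-2 but 9.86 CPM in Shigu-2 and 14.8 CPM in Vash-1, RBCS2B (AT5G38420) 4339 CPM in Kly-1 to 9391 CPM in Shigu-2, and RBCS3B (AT5G38410) 5380 CPM in Shigu-2 to 13000 CPM in Vash-1. Near-identical copies (these genes, the LHCB1 genes, KIN1 with KIN2, and COR15A with COR15B) can exchange tags in mapping, so their single values are uncertain.

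Anthocyanin and flavonoid genes were higher in Vash-1 (0.57, percentile 100) and lower in Kly-1 (−0.36, 0) and Altenb-2 (−0.39, 0.47), with 14 of 21 spanning 2-fold. DFR (AT5G42800), dihydroflavonol reductase, had 23.5 CPM in Vash-1, 10.2 CPM in Altenb-2, 7.36 CPM in Shigu-2 and 2.52 CPM in Kly-1. UF3GT (AT5G54060) and 5MAT (AT3G29590), which modify anthocyanins, had 18.0 and 13.0 CPM in Vash-1, with lows of 3.76 CPM (Shigu-2) and 1.54 CPM (Kly-1). MYB11 (AT3G62610), a flavonol regulator, had 6.58 and 6.72 CPM in Kly-1 and Vash-1 and 1.78 and 0.73 CPM in Altenb-2 and Shigu-2. Against the mean of the other sets, 7 members were 2-fold higher in Vash-1 and 0 lower. Some abundant members, named after their values were seen, went another way. CHS (AT5G13930) and CHI (AT3G55120) had 2814 and 644 CPM in Shigu-2 against 1322 and 355 CPM in Vash-1. UGT78D2 (AT5G17050) had 988 CPM in Altenb-2 and 647 CPM in Vash-1.

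**Figure D4:**
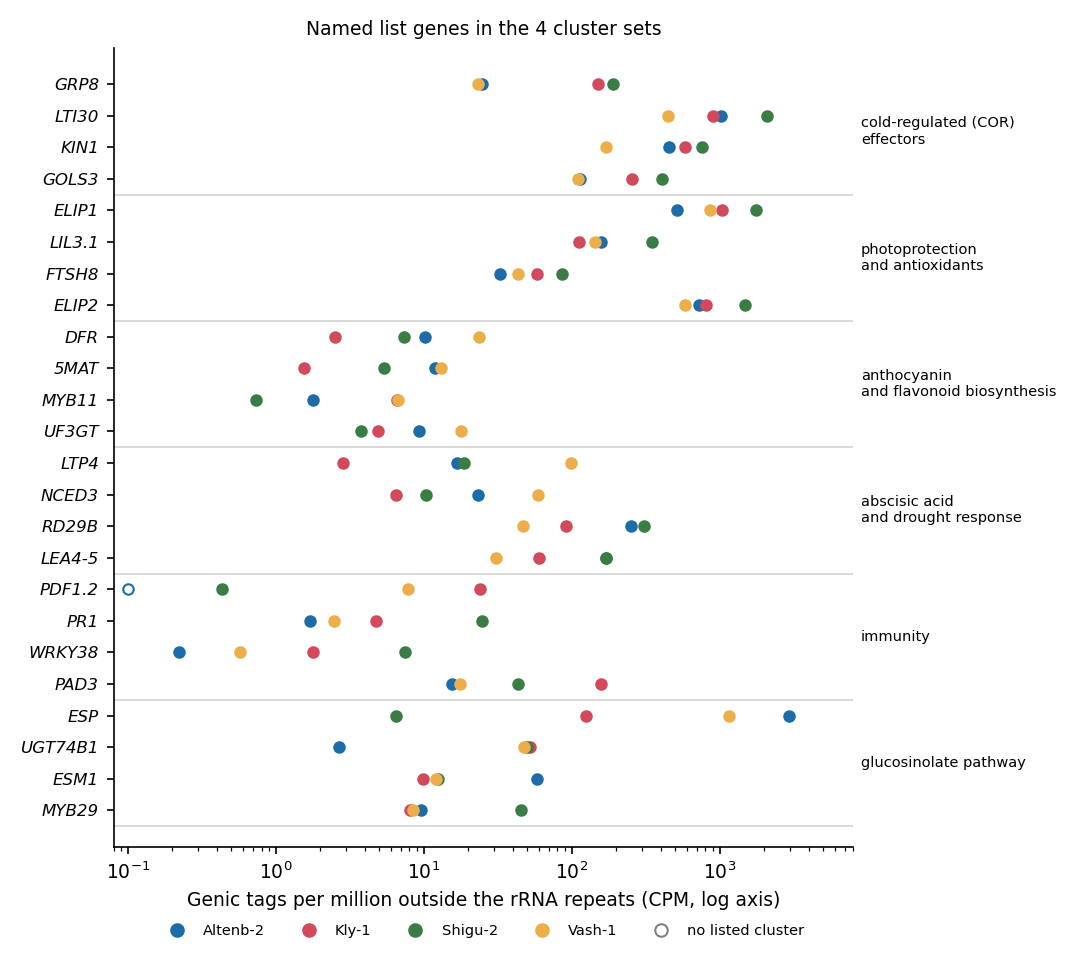
Genic tags in CPM of the tags outside the rRNA repeats (log axis) of the 4 widest-ranging members of 6 gene lists, 1 point per pooled cluster set and so without replicate error; an open circle at the left edge means that no cluster was listed. Shigu-2 is highest for all 4 cold-regulated genes shown, while Vash-1 is highest for DFR, 5MAT and UF3GT.

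Abscisic acid and drought genes had all 4 medians outside the central 95%: higher in Shigu-2 (0.86, percentile 100) and Altenb-2 (0.44, 100), lower in Vash-1 (−0.79, 0) and Kly-1 (−0.42, 0), with 13 of 16 spanning 2-fold. RD29B (AT5G52300) had 306 and 253 CPM in Shigu-2 and Altenb-2 against 91.7 CPM in Kly-1 and 46.8 CPM in Vash-1. LEA4-5 (AT5G06760), a late embryogenesis abundant protein gene, had 172 and 171 CPM against 59.8 and 30.7 CPM in the same order. The direction was not uniform: NCED3 (AT3G14440), the rate-limiting enzyme of abscisic acid synthesis, was highest in Vash-1 (58.9 CPM, against 6.45 CPM in Kly-1), as was the lipid transfer protein gene LTP4 (AT5G59310; 98.6 CPM, against 2.83 CPM). Proline, raffinose, sucrose and starch genes were lower in Vash-1 (−0.34, percentile 0), with 9 of 18 spanning 2-fold. SUS1 (AT5G20830), sucrose synthase, had 129 CPM in Vash-1 and 626 CPM in Shigu-2, and P5CS2 (AT3G55610), for proline synthesis, 116 CPM in Altenb-2 and 329 CPM in Shigu-2. ERD6 (AT1G08930), a sugar transporter gene, had 279 and 207 CPM in Kly-1 and Vash-1 and 62.1 CPM in Shigu-2, and DIN10 (AT5G20250) 63.4 CPM in Shigu-2 to 206 CPM in Kly-1.

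Heat shock genes were higher in Kly-1 (1.48, percentile 100) and lower in Vash-1 (−0.73, 0.01), with 5 of 8 spanning 2-fold. The size in Kly-1 depended on the settings, with medians of 0.74 to 1.73 over 8 alternatives, though each kept its call. HSP17.6A (AT5G12030) had 27.6 CPM in Kly-1 and 0.73 CPM in Vash-1, and HSP17.6II (AT5G12020) 27.2 CPM in Kly-1 and 4.03 CPM in Shigu-2. HSP101 (AT1G74310), a disaggregase gene, had 10.99 CPM in Kly-1 and 1.79 CPM in Vash-1. Not all members followed: the far more abundant HSP70-1 (AT5G02500), named after its values were seen, had 834 CPM in Kly-1 and 1423 CPM in Vash-1. Clock genes had no set outside the central 95%, but their range was wide (median 0.84, percentile 98.8), with 4 of 17 spanning 2-fold. PRR5 (AT5G24470) had 49.96 CPM in Shigu-2 and 12.0 CPM in Vash-1, and TOC1 (AT5G61380) 91.4 CPM in Shigu-2 and 43.8 CPM in Altenb-2.

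Immunity genes were higher in Kly-1 (0.69, percentile 100) and lower in Altenb-2 (−0.79, 0) and Vash-1 (−0.37, 0.11), with 12 of 15 spanning 2-fold. PAD3 (AT3G26830), the last enzyme of camalexin synthesis, had 159 CPM in Kly-1, 43.4 CPM in Shigu-2 and 15.5 to 17.57 CPM in the other sets. PDF1.2 (AT5G44420), a defensin gene, had 24.0 CPM in Kly-1, 7.83 CPM in Vash-1 and 0.43 CPM in Shigu-2, and was unlisted in Altenb-2. PR1 (AT2G14610), a salicylic acid marker, went another way, with 24.7 CPM in Shigu-2 against 4.74 CPM in Kly-1 and 1.69 CPM in Altenb-2, as did WRKY38 (AT5G22570; 7.49 CPM in Shigu-2, 0.22 CPM in Altenb-2).

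Glucosinolate genes were higher in Shigu-2 (0.35, percentile 98.98) and lower in Kly-1 (−0.29, 0), with 8 of 18 spanning 2-fold. UGT74B1 (AT1G24100), a glucosyltransferase of the core pathway, had 2.67 CPM in Altenb-2 and 47.3 to 52.6 CPM elsewhere. ESM1 (AT3G14210), which favours isothiocyanates over nitriles, had 57.9 CPM in Altenb-2 and 9.89 to 12.4 CPM elsewhere, and MYB29 (AT5G07690), a regulator, 45.1 CPM in Shigu-2 and 8.12 to 9.53 CPM elsewhere. Flowering time genes had no set outside the central 95% but a wide range (1.43, percentile 99.9), with 6 of 10 spanning 2-fold. MAF3 (AT5G65060), a floral repressor gene, had 125 CPM in Kly-1, 21.5 CPM in Shigu-2, 12.8 CPM in Vash-1 and 1.51 CPM in Altenb-2. Its neighbour MAF2 (AT5G65050) had 5.14 CPM in Vash-1 and 19.9 to 22.5 CPM elsewhere, and MAF5 (AT5G65080) 6.68 CPM in Vash-1 and 0.27 to 0.67 CPM elsewhere. FLC (AT5G10140), the vernalization-sensitive repressor, named after its values were seen, had 186 to 230.2 CPM.

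Ribosome and ribosome biogenesis genes moved by small amounts in many members: lower in Altenb-2 (−0.45, percentile 0.07), higher in Kly-1 (0.25, 99.96) and Shigu-2 (0.31, 99.1), with 1 of 21 spanning 2-fold (RPL9D, AT4G10450; 102 CPM in Kly-1, 40.96 CPM in Vash-1). NOP56 (AT1G56110), a nucleolar protein gene, had 85.5 CPM in Altenb-2 and 155 CPM in Shigu-2. The rRNA share was again highest where the list was lowest (54.6% in Altenb-2) and lowest in Shigu-2 (40.8%). Cell expansion genes had no median outside the central 95% (8 of 20 spanned 2-fold; XTH22, AT5G57560, 41.5 CPM in Vash-1 and 6.77 CPM in Shigu-2), nor had cell cycle genes (3 of 6). In the latter, TSO2 (AT3G27060), a ribonucleotide reductase gene, had 8.84 CPM in Vash-1 and 39.4 to 57.3 CPM elsewhere, and MCM5 (AT2G07690), of the replication helicase, 6.52 CPM in Vash-1 and 24.4 to 26.2 CPM elsewhere.

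Common reference genes had no median outside the central 95%, but 2 of 8 spanned 2-fold. UBQ10 (AT4G05320), a polyubiquitin gene, had 21.8 CPM in Vash-1 and 152 to 275 CPM elsewhere, and UBC21 (AT5G25760) 30.6 CPM in Shigu-2 and 8.55 to 12.0 CPM elsewhere. ACT7 (AT5G09810) and EF1A (AT5G60390) were steadier, at 524 to 809 CPM and 1234 to 1820.1 CPM.

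Markers of other tissues were mostly low. Of the 10 root markers, 4 were measured in the list comparison, with a lower median in Shigu-2 (−0.52, percentile 1.72). PYK10 (AT3G09260), a root-enriched glucosidase gene, had 421 CPM in Shigu-2 to 839 CPM in Kly-1, and TIP2.2 (AT4G17340) 8.19 CPM in Kly-1 to 18.1 CPM in Vash-1. Of 8 flower markers 2 were listed and 0 reached 5 CPM, and of 10 seed markers 8 were listed and 1 reached 5 CPM (EM1, AT3G51810, 5.32 CPM in Shigu-2). No median of the guard cell, phloem or epidermis lists lay outside the central 95%. MYB60 (AT1G08810) of guard cells had 7.70 CPM in Altenb-2 and 15.4 to 16.4 CPM elsewhere, and PDF2 (AT4G04890) of the epidermis 137 CPM in Altenb-2 and 50.2 to 59.5 CPM elsewhere. The phloem gene SUC2 (AT1G22710), a sucrose carrier, had 25.3 CPM in Shigu-2 and 19.3 CPM in Altenb-2. In the shoot meristem list, 1 of 5 markers reached 5 CPM: KNAT1 (AT4G08150), from 0.93 CPM in Altenb-2 to 6.2 CPM in Vash-1.

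The fourth question is whether genes with several promoters used them in the same proportions. Of 9774 genes with at least 2 genic loci and 50 tags in each set, 500 (5.12%) had a different main locus in at least 1 set, and in 93 of these, or 0.952% of the 9774, a locus changed its share by 50 percentage points or more. Counting error alone, simulated over 10419 genes, gave 210 and 0. INDH (AT4G19540; chromosome 4, plus strand), which serves complex I assembly in mitochondria, started mainly at 10657323 to 10657408 in Altenb-2 (80.0% of its genic tags, 75.1 to 84.3%), Kly-1 (79.5%) and Shigu-2 (88.3%). In Vash-1 all 54 tags came from the downstream locus at 10657448 to 10657482, so the upstream share was 0 (0 to 6.60%). AT1G03106 used a locus at chromosome 1 positions 749005 to 749027 in Kly-1 (98.6%) and Vash-1 (94.5%), whereas in Shigu-2 89.3% of its tags came from 748761 to 748867, 173 bp inside the gene start. In Altenb-2 (85 tags) these 2 loci held 11.8% and 0, so most of its tags came from neither. AT2G40020 started at chromosome 2 positions 16710962 to 16711009 in 3 sets (96.6% or more) and at 16711023 to 16711037 in Vash-1 (100% of 80 tags). ABCG21 (AT3G25620), a transporter gene, moved to a single position, 9319540 on chromosome 3, in Shigu-2 (78.7% of 75 tags, and 0 elsewhere). AT3G43610 used 15523976 to 15524003 on the same chromosome for all 70 tags in Shigu-2 and for 0 of 200 to 775 tags elsewhere. The counts depended on how clusters were joined: 3296 genes with a different main locus and 2798 with a 50-point change with peaks chained within 10 bp, and 71 and 19 within 100 bp. With 200 tags required in each set they were 164 and 23. The named examples depend on this joining too. The 2 peaks of INDH, AT2G40020, ABCG21 and AT3G43610 lie under 100 bp apart, so chaining within 100 bp would make each pair 1 locus.

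**Figure D5:**
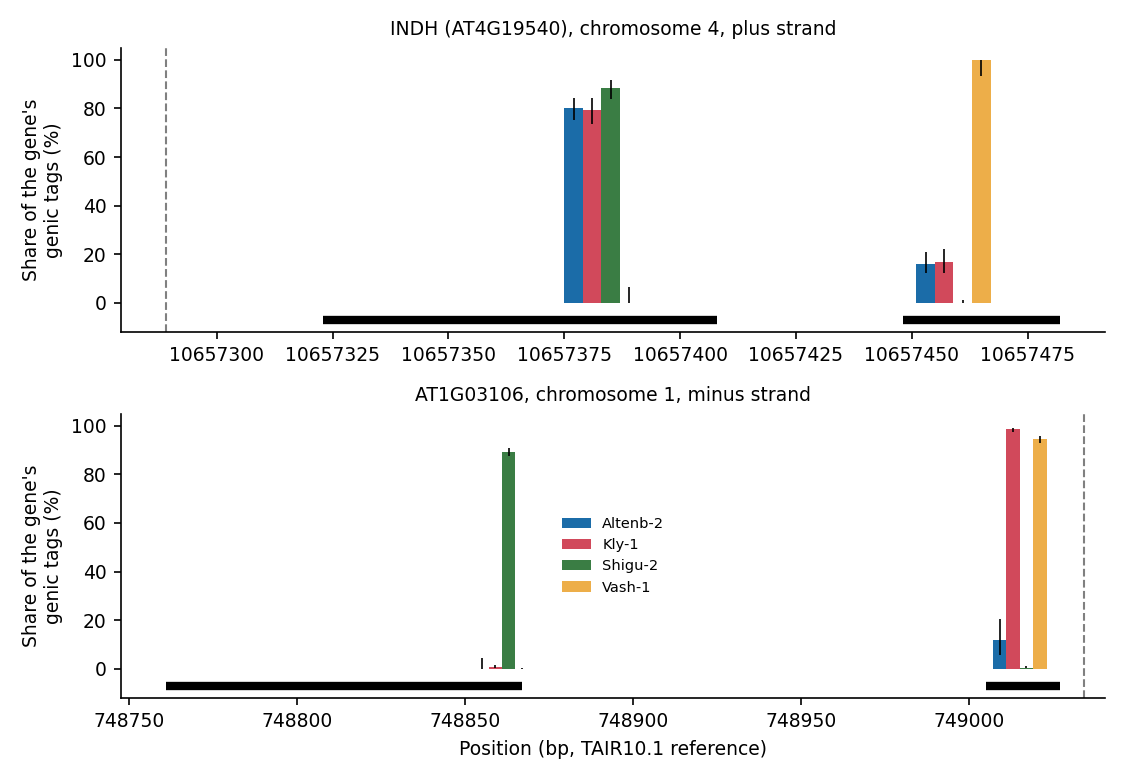
Share of the genic tags of INDH (upper, chromosome 4) and AT1G03106 (lower, chromosome 1) at each of 2 start site loci in the 4 cluster sets, against position (bp, TAIR10.1 reference). Bars start at 0 and stand side by side at each locus, with exact binomial intervals; black strips mark the extent of each locus and the dashed lines the annotated gene starts. In Vash-1 the upstream INDH locus has 0% of the tags, against 79.5 to 88.3% in the other sets.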

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

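Of the tests below, those of abundance at antisense and intergenic loci and at intragenic loci, of sequencing depth, of scattered background and of promoters inside genes were chosen after the result was seen. The tests on abundance at all non-genic loci, on intragenic fragments, on opposite-strand reads and on introns were chosen before.

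The rRNA repeats, which lie outside the comparisons, held 54.6% of the tags in Altenb-2, 44.3% in Kly-1, 40.8% in Shigu-2 and 53.1% in Vash-1; they stand out because data left aside held this much signal. No control without capped RNA is at hand, so the values are given without explanation.

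Non-genic loci reached 1 CPM in all 4 sets less often than genic loci. Most of this gap was gone at matched abundance. The matching used the same levels that decide detection, so it can also hide part of a real gap. Simulated counting error alone gave 89.9% of genic and 71.8% of non-genic loci in all 4 sets, a smaller gap than the real one. Those draws hold no variation between sets, so the smaller gap does not decide whether abundance explains the real one. The interval of the 2.08 points left (1.12 to 3.07) lay above 0, the limit set before. By the limit set afterwards, the 2.08 points were above all of 100 draws with counting error alone (up to 1.53), but their interval was not. The difference was 1.68 with 50 bins and 1.38 with rRNA repeats kept, so this value alone decides little. Abundance as the whole cause is argued against by antisense and intergenic loci, where 8.75 points were left (6.52 to 10.8) and the draws reached 2.82; these points also argue against fragments of mRNA inside genes as the sole cause. With peaks chained within 10 bp, however, this value was 0.991 and its interval held 0. For intragenic loci fewer tags stay open as the whole cause: 0.0807 points were left (−0.938 to 0.992; draws −0.726 to 1.62), although 5 alternatives gave intervals above 0. Divergence of accession sequences from the reference, and a different mix of treatments in the pools, could each produce it and stay open, as does a lower genetic stability of antisense and intergenic promoters, which may be examined with accession genomes.

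Altenb-2 had the most antisense and intergenic clusters at the fewest tags outside the rRNA repeats (8442, against 5078, 7060 and 5605 in Kly-1, Shigu-2 and Vash-1). Depth is argued against by these numbers, since Altenb-2 had the fewest tags. After thinning to equal tags Altenb-2 had 1.69 times the next highest set. Thinning left Altenb-2 unchanged and could only lower the other sets, so it adds no test of its own. Opposite-strand reads of abundant transcripts are argued against as the sole source: 10.6% of its antisense clusters (9.88 to 11.3%) lay in the highest of 10 bins of genes by sense level, below the 13.1 to 13.9% of the other sets. A contribution from them stays open, because this share also falls when other antisense clusters are added. In number, 762 lay in that bin at the fewest tags, against 585, 839 and 624 in Kly-1, Shigu-2 and Vash-1. Scattered background stays open. After thinning, Altenb-2 had 4223 clusters more than the mean of the other sets (4219), but which clusters are the excess is not known. Of all its antisense and intergenic clusters, 49.98% carry a pyrimidine-purine peak. If a number equal to that mean carries it at the 69.2% of the other sets, 30.7% (28.6 to 32.9%) of the excess would. This value lies between the 21.1% of positions 50 bp away and the 69.2%, so the excess may mix background with real starts. A property of the accession was not tested apart from its pool.

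Peaks of intragenic clusters lacked the pyrimidine-purine initiator more often than genic peaks. Fragments of spliced transcripts, for example recapped or incompletely captured ones, are a candidate explanation: introns held 4.58% of the clusters at 30.3% of the length. Against fragments spread evenly along transcripts, 3′ untranslated regions, which spliced transcripts also hold, had 1.01% of the clusters at 14.0% of the length. Promoters inside genes are a candidate for the most abundant ones, since 85.3% of intragenic clusters of 1000 or more tags had the initiator, near the 90.11% of genic clusters and far from the 45.8% of intragenic clusters in all. By place, the initiator was at 44.3% of peaks in coding sequence, 46.2% in 3′ untranslated regions and 70.1% in introns (68.7 to 71.3%). GG was at 24.3, 12.1 and 2.11% in the same order, so both differences from genic peaks were larger in exonic sequence. Both explanations may hold side by side, and no treatment comparison could separate them here. The class limit was the most upstream annotated start codon of a gene. The ordinary promoter of an isoform with a later start codon is therefore counted as intragenic too, and such cases were not set apart.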

How the results depend on the processing

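Alternatives with 20 or 50 bins, peaks chained within 10 or 100 bp, bins on the highest set, initiator peaks alone, a set left out, rRNA repeats kept, other pseudocounts, no minimum or 20 CPM, 200 tags and the median of ratios were chosen after the data were seen. No paired analysis was possible because the deposited columns carry no replicate numbers or libraries. For the same reason the alternatives first intended, of size factors, count filters, another count model, replicate blocks, single groups, minimum fold, libraries left out, other gene set tests and genes called in a test were not run. The cause was not tested for the changes below unless one is named.

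The genic share of tags was 93.2% with a 200 bp window, 93.5% after thinning and 48.9% with rRNA repeats kept. The matched difference of genic and non-genic loci stayed above 0 in all 17 alternatives (1.38 to 5.97 points), but simulated counting error alone reached 1.53. That of genic minus antisense and intergenic loci fell to 0.991 with peaks chained within 10 bp and otherwise kept its call (up to 19.4). Genic minus intragenic loci passed 0 at 5 CPM (2.33), with 5 bins (1.16), with peaks chained within 10 bp (1.79) and 100 bp (1.98), and with bins on the highest set (2.14). The shares found in all sets ranged over 41.4 to 84.8% for genic and 16.6 to 54.7% for non-genic loci. The peak position difference stayed above 0 in 19 alternatives (2.69 to 15.9 points). The other pseudocounts among these do not enter the comparison of peak positions, so they count as unchanged by construction. Thinning redrew tag counts but kept the deposited peak position of each cluster. It therefore could not show whether peaks within a cluster shift with depth.

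Losses of strong loci numbered 1565 with peaks chained within 10 bp, where neighbouring starts of 1 promoter become separate loci, and 5 with rRNA repeats kept. Genes with a different main locus were 3296 (2798 with a 50-point change) within 10 bp, 71 (19) within 100 bp and 164 (23) at 200 tags. Without a minimum CPM, genes differing 2-fold were 1576 in Altenb-2, 1356 in Kly-1, 1610 in Vash-1 and 5426 by range. At 20 CPM, where fewer genes enter, they were 447, 399, 497 and 497 in Altenb-2, Kly-1, the Shigu-2 set and Vash-1, and 1570 by range. The share of higher genes among these calls moved with scaling: with the median of ratios and with rRNA repeats kept it was 49.8 and 18.202% in Altenb-2 (35.9% as reported), 55.6 and 70.4% in Kly-1 (59.6%), 37.2 and 74.8% in Shigu-2 (51.1%) and 51.5 and 31.9% in Vash-1 (46.5%). Of 704 list medians under alternatives, 701 stayed inside or outside the central 95% as before, 2 lost their call (cold-regulated effectors in Kly-1, 0.12, thinned; cold and light regulators in Vash-1, −0.38, rRNA repeats kept) and 1 reversed, the Calvin cycle in Shigu-2, at 0.0606 with rRNA repeats kept, which shifts all genes of that set by 0.27. In all 33 medians changed sign, 17 with rRNA repeats kept and 12 with the median of ratios, which move all genes of a set alike and so say little about the lists. Single-gene log2 differences moved by over 0.5 in 23 of 95 cases. The settings of no minimum and 20 CPM enter neither the list medians nor these differences. Both settings therefore count as unchanged by construction in the 704 and the 95.

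Depth limits the low end: at 0.134 to 0.223 CPM per listed cluster, absence below 1 CPM is not evidence of loss, and antisense and intergenic loci, with medians near 1 CPM, are the least certain.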

Other observations

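The test of TATA loci below was chosen after the data were seen.

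Promoters with a TATA motif varied more between the sets than those without. Among genic loci found in all 4 sets, 27.6% of TATA loci had an SD of log2 level of 0.5 or more, against 12.9% of loci without the motif at matched abundance, a difference of 14.6 points (13.0 to 16.2) that lay between 11.7 and 15.5 over 19 alternatives. Found in all 4 sets were 72.5% of TATA loci and 74.6% of the others at matched abundance, a difference of −2.11 points (−2.86 to −1.38). Runs of pyrimidines went with slightly less variation, by −1.79 points (−2.71 to −0.743). TATA clusters were also sharper: among genic clusters of 1000 or more tags in Altenb-2, the median width was 69 bp with the motif and 107 bp without, and the peak held 57.6 against 35.3% of the tags. In Shigu-2 the widths were 75 and 110.0 bp. Antisense clusters in pseudogenes numbered 720 of 7213 in Altenb-2, 203 of 4271 in Kly-1, 296 of 6047 in Shigu-2 and 360.0 of 4758 in Vash-1.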
